A study of Homo sapiens with 6 samples.

How the data were processed

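RNA-seq libraries were made from HEK293T cells grown in DMEM, per the labels' protocols, in 3 groups of 2 libraries: wild type and a pair of MED23 knockdowns. RNA was extracted with TRIzol, polyadenylated RNA was selected and strand-specific libraries were built with a directional NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, STAR, RSEM and DESeq2, with no versions, and the builds hg19 and GRCh37. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain.

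A single headerless table of 20 columns was used, with GENCODE release 19 as its annotation per its name. Coordinates, gene symbols and gene types were taken from that table on hg19. The mean normalized count per gene, a signal never below 0, was deposited by the authors. The log2 fold change and its standard error, also on the log2 scale, were computed and deposited by the authors. A Wald score, a p-value and an adjusted p-value per gene were deposited by the authors as well. Because the columns have no header, what they hold was checked by arithmetic: the Wald score equalled the log2 fold change over its standard error, and the p-value its normal tail probability, in every gene with a p, within 1.42e-13 and 2.72e-15. Which arm is the numerator of the fold change is not given in the sources used here, and no direction was assigned to knockdown or wild type. The 6 further columns of values per library carry no name that matches a sample label, and none of them entered a result. They were looked at while the format of the table was worked out, and the levels of MED23 and AMOT seen there did not follow the pattern of a simple MED23 knockdown if the columns were in the order of the sample labels. The deposited fold change also appeared to set more of these columns on the numerator side than on the denominator side, and MED23 did not look alike in all columns of the numerator, so a numerator value may pool libraries of unlike kinds. The order of the columns is not known, so whether the labels are right, and whether some cells carried another change in MED23 or AMOT, is open for every value given for these genes.

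The tests set before the data were examined needed values per library and could not be used: edgeR was not run, and each knockdown was not compared with wild type or with the other. The authors' deposited comparison took their place. A change was called at an adjusted p under 0.05 as deposited. The table gave a p for 27176 genes and an adjusted p for 17687 genes, the lowest mean normalized count among the latter being 6.83. Intervals of 95% are the log2 fold change plus and minus 1.96 standard errors. Levels in CPM are the mean normalized count scaled by its sum over all genes, with 1 CPM equal to a mean normalized count of 28.2. Depth per library is unknown, so no interval of counting error is given.

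The 28 gene lists and the rule for named genes were fixed before the data were examined. The lists held Mediator subunits, immediate early genes, actin and MRTF-SRF genes, YAP/TEAD targets, cholesterol genes, fatty acid genes, interferon-stimulated genes, ATF4 targets, unfolded protein response genes, heat shock genes, p53 targets, G1/S genes, G2/M genes, H2B ubiquitination and elongation factors, splicing factors, glycolysis genes, oxidative phosphorylation genes, ribosomal proteins, RNA polymerase I and ribosome biogenesis genes, matrix genes, epithelial and kidney markers, neuronal markers, blood cell markers, histones, mitochondrially encoded transcripts, metallothionein and NRF2 genes, WNT targets and TGF-beta/BMP targets. Named were MED23, then the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes of at least 1 CPM, then per list up to 4 called members with the smallest p, or up to 2 members with the highest level where none was called. The rule's parts on separate knockdowns could not be applied, and some genes that the rule names are not reported here.

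Each list was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald score, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists that had members with an adjusted p. Members were also adjusted over the list alone. The step was tested on simulated independent normal scores of 17687 genes, with 27 lists of random genes that had the sizes of the tested lists. No gene was in more than 1 of these lists. With 5 lists shifted by 0.8 SD in 200 replicates, 80.8% of shifted lists and 0.523% of the others were called. The simulated scores were not correlated within lists, so these shares do not show how often lists of genes regulated together are called wrongly. Other calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.

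For GC content and transcript length, gene identifiers were matched to the transcripts of GENCODE release 29, which found 17119 genes (96.8%); no coordinate was taken from that release. Log2 fold changes limited to an absolute size of 3 were regressed on GC content, length and mean level with polynomials of degree 3, which explained 5.53% of their variance. Random lists of like level were drawn 10000 times per list from 20 level bins. Chromosome medians were tested with 1000 shuffles of gene positions over genes of at least 1 CPM, and windows held 25 neighbouring genes, or more at the end of a chromosome.

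Alternatives tried were an adjusted p over all genes with a p or over protein-coding genes only, an absolute log2 fold change of at least 1, an adjusted p under 0.01, a mean of at least 10 CPM and fold changes centred on their median. For the lists, a preset correlation of 0.05, ranks, regression residuals, random lists of like level and chromosome medians subtracted were tried.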

Results

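Polyadenylated RNA was sequenced from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen and is widely used for transfection. The labels describe 6 libraries in 3 groups of 2: wild-type cells and a pair of knockdowns of MED23, a tail-module subunit of Mediator, the complex that links transcription factors to RNA polymerase II. How MED23 was knocked down, and whether the 2 libraries of a group came from separate cultures, is not given in the sources used here. The p-values may therefore measure technical spread only or, where an arm pools libraries of unlike kinds, also differences between those kinds. The values come from a single comparison in the authors' deposited table, which held 27179 genes with a log2 fold change, its standard error (SE) and p-values. The table's columns name neither arm of that comparison. A positive fold change is therefore higher on the numerator side and a negative one lower there, without either side being assigned to knockdown or wild-type cells. The 6 columns of values per library carry no names and were not used, so the knockdowns were not compared with each other and depth per library is unknown. Levels are also given in CPM, the mean normalized count over libraries scaled by its sum over all genes, so that 1 CPM corresponded to a mean normalized count of 28.2.

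The targeted gene was examined before any other. MED23 (ENSG00000112282.13, chromosome 6, 131895106 to 131949369, hg19) had a mean normalized count of 7720 and a log2 fold change of 1.81 ± 0.97 (SE) in the authors' deposited table, with a 95% interval of -0.09 to 3.70 and an adjusted p of 0.197. The difference in MED23 between the arms did not pass the test, and the positive sign of its estimate does not tell which arm held the knockdowns. The estimate is a mean over an arm that may pool unlike libraries, and a reduction of MED23 in the libraries labelled as knockdowns was not established here, so the labels remain unchecked for every comparison that follows. Its standard error was 8.28 times the median of 0.117 among the 1001 genes of nearest mean level, where it ranked 4 from the highest. The remaining Mediator subunits differed little, with 2 positive, 2 negative and 27 not past the test among 31 measured. MED13, a kinase-module subunit, stood at 0.55 ± 0.12 (SE) and MED11, a head-module subunit, at -0.51 ± 0.16 in the authors' deposited table. Adjusted over the list alone, 1 was positive and 2 were negative, and the list as a whole did not pass the competitive gene-set test (cameraPR adjusted p = 0.637). MED15, a tail-module subunit at 0.33 ± 0.13 in the authors' deposited table, had an adjusted p of 0.0474, which became 0.0720 when adjusted over all genes with a p.

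Interferon-response genes were far higher on the numerator side. Values per library were not used, so whether all libraries of that side shared this is not known. Of the 12 genes named for the largest negative changes, AMOT, which encodes a scaffold protein of the Hippo pathway, had by far the highest mean level. Of 17687 genes with an adjusted p in the authors' deposited table, 3196 (18.1%) were under 0.05, of which 1730 were positive and 1466 negative. The share of positive changes was 54.1%, and it was 69.6% among the 677 of these genes with an absolute log2 fold change of at least 1 (471 positive and 206 negative). By gene type, 2893 were protein-coding (1589 positive, 1304 negative), 100 were lincRNAs (47 and 53), 92 antisense genes (48 and 44), 62 pseudogenes (22 and 40) and 49 of other types (24 and 25).

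**Figure D1:**
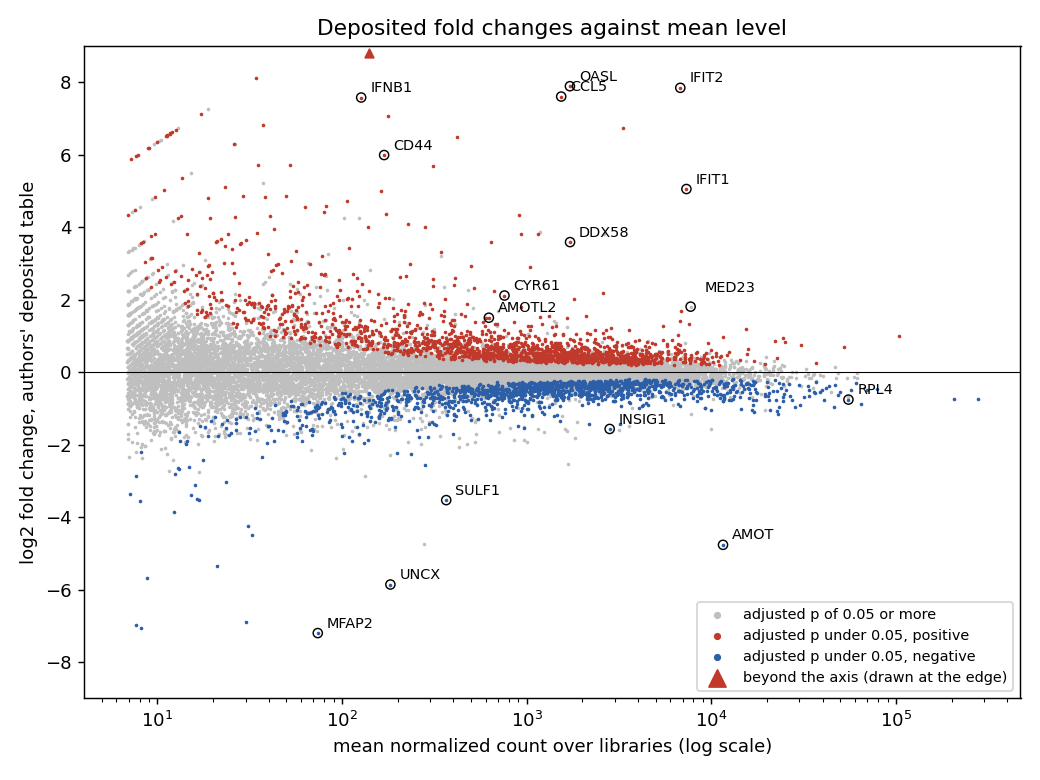
Log2 fold change in the authors' deposited table (vertical axis) against mean normalized count over libraries (horizontal log axis) for the 17687 genes with an adjusted p, one point per gene. Red and blue points are the 1730 positive and 1466 negative genes with an adjusted p under 0.05, grey points the rest, and circles mark labelled genes. MED23 lies at 1.81 among the grey points, AMOT at -4.77, and SAGE1 at 22.87 is drawn as a triangle at the upper edge.

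The largest positive changes among genes of at least 1 CPM were mostly of antiviral and chemokine genes. IFNB1, which encodes interferon beta, stood at 7.58 ± 1.11 (SE) on the log2 scale in the authors' deposited table (adjusted p = 8.31e-10). The chemokine genes CCL5 and CXCL10 stood at 7.60 ± 0.77 and 7.06 ± 0.76, and the antiviral genes OASL, IFIT2, RSAD2, IFIT3 and OAS3 at 7.89 ± 0.91, 7.84 ± 0.99, 6.81 ± 1.48, 6.74 ± 0.42 and 6.49 ± 0.57 in the authors' deposited table. The standard error of IFIT2 was 8.67 times the median of genes of like level. CD44, a hyaluronan receptor, had 5.99 ± 0.86, and CPA4, a carboxypeptidase, 5.71 ± 1.21 in the authors' deposited table. KRT17, a keratin gene whose reads near-identical copies may share, had 8.12 ± 1.65 in the authors' deposited table and is uncertain. The entry of SAGE1 in the authors' deposited table, 22.87 ± 4.21, is a fitted value that gives no measure of size (adjusted p = 2.34e-06).

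Among 30 measured interferon-stimulated genes, 24 were positive, none was negative and 6 did not pass the test. Adjusted over the list alone, 26 were positive. The list median was 2.57 on the log2 scale, and the list passed cameraPR with an adjusted p of 3.37e-51. DDX58 and IFIH1, which encode the cytosolic RNA sensors RIG-I and MDA5, had log2 fold changes of 3.59 ± 0.13 (SE) and 4.33 ± 0.30 in the authors' deposited table. IFIT1 (chromosome 10, 91152303 to 91163745, hg19) was 33.2-fold higher on the numerator side in the authors' deposited table (log2 5.05 ± 0.21, adjusted p = 5.53e-130).

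AMOT (chromosome X, 112017731 to 112084043, hg19), which encodes angiomotin, a binding partner of the transcriptional coactivator YAP, was 27.2-fold lower on the numerator side in the authors' deposited table. Its log2 fold change was -4.77 ± 0.10 (SE) at a mean normalized count of 11560, and its adjusted p is listed as 0 in the authors' deposited table. Among 16 measured target genes of YAP and its partner TEAD, 6 were positive, none was negative and 10 did not pass the test. Adjusted over the list alone, 8 were positive (list median 0.35, cameraPR adjusted p = 5.56e-11). The matricellular genes CTGF and CYR61 stood at 2.99 ± 0.25 and 2.11 ± 0.16, and AJUBA, a LIM-domain gene, at 1.28 ± 0.14 in the authors' deposited table. AMOTL2, a paralog of AMOT, was 2.83-fold higher on the numerator side in the authors' deposited table (adjusted p = 1.26e-34).

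The other genes with the largest negative changes came from several functions. MFAP2, a microfibril gene, had -7.20 ± 0.68 (SE), BEX1 -6.90 ± 0.98 and UNCX, a homeobox gene, -5.86 ± 0.42 on the log2 scale in the authors' deposited table. CDO1, which encodes cysteine dioxygenase, had -4.50 ± 0.77, the inositol phosphatase gene INPP5D -4.24 ± 0.68, the heparan sulfate endosulfatase gene SULF1 -3.53 ± 0.28 and the transcription factor gene SNAI2 -2.55 ± 0.51 in the authors' deposited table. The remaining named genes were ADCYAP1R1, the receptor gene of the neuropeptide PACAP, with -2.26 ± 0.33, FAM150A with -2.25 ± 0.30 and MYOM2, a sarcomere gene, with -2.24 ± 0.27 in the authors' deposited table. The pseudogene RPL35P1, at -2.35 ± 0.89 in the authors' deposited table, is uncertain because reads of its parent gene may be shared with it, and its adjusted p of 0.0470 became 0.0715 when adjusted over all genes with a p.

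Genes for protein synthesis and mitochondrial respiration were lower on the numerator side. Of 37 cytosolic ribosomal protein genes, 32 were negative, none was positive and 5 did not pass the test, and adjusted over the list alone 34 were negative (median -0.59, cameraPR adjusted p = 1.78e-32). RPL3 and RPL4 had -0.96 ± 0.11 (SE) and -0.76 ± 0.07, and RPL11 and RPS4X -0.75 ± 0.09 and -0.56 ± 0.07 in the authors' deposited table; many of these genes have processed pseudogenes that may share their reads. After regression on GC content, transcript length and mean level, the median of the ribosomal protein list was -0.27. Of 28 genes for RNA polymerase I and ribosome biogenesis, 15 were negative, none was positive and 13 did not pass the test, with 16 negative adjusted over the list alone (median -0.33, cameraPR adjusted p = 6.22e-07). The nucleolar genes GNL3 and FBL stood at -0.81 ± 0.15 and -0.59 ± 0.07, and RRP1B and PES1 at -0.34 ± 0.07 and -0.34 ± 0.09 in the authors' deposited table. Of 32 nuclear-encoded genes for oxidative phosphorylation, 12 were negative, none was positive and 20 did not pass the test, with 15 negative adjusted over the list alone (median -0.28, cameraPR adjusted p = 2.55e-07). That median was -0.14 after regression on the same 3 properties. CYC1 of respiratory complex III had -0.62 ± 0.09 and ATP5A1 of ATP synthase -0.50 ± 0.08 in the authors' deposited table. Of 26 splicing factor genes of the hnRNP and SR families, 7 were negative, none was positive and 19 did not pass the test, with 9 negative adjusted over the list alone (median -0.18, cameraPR adjusted p = 1.64e-04). HNRNPA1, which has processed pseudogenes, stood at -0.89 ± 0.21, and SRSF5 at -0.53 ± 0.07 in the authors' deposited table. The call of the splicing factor list was lost on the residuals of that regression (adjusted p = 0.279) and against random lists of like level (adjusted p = 0.278).

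Chaperone genes of the endoplasmic reticulum and the cytosol were higher on the numerator side. Of 20 genes of the unfolded protein response of the endoplasmic reticulum, 12 were positive, none was negative and 8 did not pass the test, with 14 positive adjusted over the list alone (median 0.54, cameraPR adjusted p = 9.17e-09). CALR and HSP90B1, which encode luminal chaperones, had 0.93 ± 0.15 (SE) and 0.73 ± 0.08 in the authors' deposited table. Of 15 cytosolic heat shock genes, 7 were positive, none was negative and 8 did not pass the test, with 7 positive also adjusted over the list alone (median 0.48, cameraPR adjusted p = 0.00120). HSP90AA1 stood at 0.98 ± 0.16 and BAG3, a co-chaperone gene, at 0.80 ± 0.10 in the authors' deposited table. Target genes of ATF4 in the integrated stress response were mixed, with 3 positive, 9 negative and 15 not past the test among 27, and the same counts adjusted over the list alone (median -0.33, cameraPR adjusted p = 0.0163). MTHFD2, of mitochondrial folate metabolism, had -0.75 ± 0.12 and FAM129A 2.24 ± 0.22 in the authors' deposited table. The negative call of this list was lost with a preset correlation of 0.05 (adjusted p = 0.103) and on the regression residuals (adjusted p = 0.0515).

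Genes of cholesterol synthesis and uptake were lower on the numerator side, with 12 negative, 1 positive and 9 not past the test among 22. Adjusted over the list alone, 14 were negative and 1 was positive (median -0.42, cameraPR adjusted p = 1.65e-07). INSIG1, a regulator of the sterol pathway, stood at -1.57 ± 0.29 (SE), SQLE, a squalene epoxidase gene, at -0.63 ± 0.08 and ACAT2 at -0.52 ± 0.09 in the authors' deposited table. Genes of fatty acid synthesis and lipid storage went both ways, with 5 positive, 4 negative and 10 not past the test among 19 and the same counts adjusted over the list alone (cameraPR adjusted p = 0.571). LPL, a lipoprotein lipase gene, had 2.04 ± 0.29, whereas SCD, a stearoyl-CoA desaturase gene, had -0.98 ± 0.18 and SREBF1 -0.78 ± 0.16 in the authors' deposited table. Glycolysis and hypoxia genes showed 2 positive, 4 negative and 22 not past the test among 28, unchanged in number adjusted over the list alone (cameraPR adjusted p = 0.637), with ENO2 at 1.17 ± 0.09 and HK2 at -0.79 ± 0.13 in the authors' deposited table. Metallothionein and NRF2 target genes had 3 positive, 2 negative and 10 not past the test among 15, and 4 positive and 3 negative adjusted over the list alone. NQO1 stood at 1.58 ± 0.48 and TKT at -0.73 ± 0.07 in the authors' deposited table. The mean of that list was 0.19 while its median of -0.03 and its test were negative (cameraPR adjusted p = 0.781).

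Growth and cell-cycle lists were mixed. Of 32 immediate early genes of the growth-factor response, 7 were positive, 1 was negative and 24 did not pass the test, with the same counts adjusted over the list alone (median 0.23, cameraPR adjusted p = 0.0843). ZFP36 had 1.29 ± 0.23 (SE), JUNB 1.12 ± 0.17 and MYC -1.44 ± 0.30 in the authors' deposited table. Actin cytoskeleton and smooth muscle genes of the MRTF-SRF pathway had 3 positive, 1 negative and 16 not past the test among 20, again with the same counts adjusted over the list alone (cameraPR adjusted p = 0.167). TGFB1I1 stood at 1.19 ± 0.24 and ACTA2, smooth muscle actin, at -1.04 ± 0.28 in the authors' deposited table. Of 28 genes of the G1/S transition and DNA replication, 2 were positive, 7 negative and 19 not past the test, with 2 positive and 8 negative adjusted over the list alone (cameraPR adjusted p = 0.0551). TK1, thymidine kinase, had 0.69 ± 0.08 and RRM2, a ribonucleotide reductase subunit, -0.61 ± 0.08 in the authors' deposited table. Of 28 G2/M genes, 5 were positive, none was negative and 23 did not pass the test, with 5 positive also adjusted over the list alone (median 0.11, cameraPR adjusted p = 0.0392). CDC25B, a mitotic phosphatase gene, stood at 0.71 ± 0.10 in the authors' deposited table, and the G2/M call was lost with a preset correlation of 0.05 (adjusted p = 0.181). It was also lost against random lists of like level (adjusted p = 0.0518) and with chromosome medians subtracted (adjusted p = 0.0690), but kept on ranks (adjusted p = 0.0329) and on the regression residuals, where the median was 0.25 (adjusted p = 1.55e-04). Of 23 p53 target genes, 2 were positive, 8 negative and 13 not past the test, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.0608), and TP53I3 had 1.02 ± 0.19 against -0.46 ± 0.13 for DDB2 in the authors' deposited table. Of 25 genes for H2B ubiquitination and elongation, 6 were positive, 1 was negative and 18 did not pass the test, unchanged in number adjusted over the list alone (cameraPR adjusted p = 0.0843). HEXIM1, an inhibitor of the elongation factor P-TEFb, stood at 0.70 ± 0.16 and SUPT5H, an elongation factor gene, at 0.30 ± 0.08 in the authors' deposited table.

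Lineage markers and developmental signalling genes were tested because a culture may hold cells of another kind or state. Of 18 neuronal markers, 6 were positive, 4 negative and 8 not past the test, with the same counts adjusted over the list alone (median 0.53, cameraPR adjusted p = 0.0217). MAP2, a microtubule-associated protein gene, had 2.26 ± 0.31 (SE), L1CAM, an adhesion gene, 2.11 ± 0.27 and ELAVL2 -0.60 ± 0.12 in the authors' deposited table. The call of the neuronal list was lost with a preset correlation of 0.05 (adjusted p = 0.101) and on ranks (adjusted p = 0.197). Of 25 extracellular matrix and mesenchymal genes, 5 were positive, 2 negative and 18 not past the test, with the same counts adjusted over the list alone (cameraPR adjusted p = 0.132). The matrix gene TNC stood at 2.92 ± 0.23 and VIM, vimentin, at 0.87 ± 0.07 in the authors' deposited table. THBS1, also a matrix gene, stood at 3.62 ± 1.03 but had a mean level of only 0.75 CPM. SNAI2, a transcription factor gene of mesenchymal cells, went the other way at -2.55 ± 0.51 in the authors' deposited table. Of 16 epithelial and kidney tubule markers, 1 was positive, KRT18 with 0.63 ± 0.18 in the authors' deposited table, and 15 did not pass the test, also adjusted over the list alone. The median of that list was -0.05, while its mean of 0.14 and its test were positive (cameraPR adjusted p = 0.742). None of the 4 blood cell markers with an adjusted p passed the test, over all genes or adjusted over the list alone (cameraPR adjusted p = 0.669), and CD8A had 0.18 ± 0.40 in the authors' deposited table. Of 11 replication-dependent histone genes, 1 was positive and 10 did not pass the test, with the same count adjusted over the list alone (median 0.94, cameraPR adjusted p = 0.178). Of these genes 90.9% had a fold change above 0, and HIST2H2BE had 1.84 ± 0.55 in the authors' deposited table. Of 15 WNT target genes, 2 were positive, 3 negative and 10 not past the test, and 3 were positive and 4 negative adjusted over the list alone. DKK1, a secreted WNT antagonist, stood at 1.27 ± 0.34 and CCND1, cyclin D1, at -1.17 ± 0.15 in the authors' deposited table. The mean of the WNT list was 0.03 while its median of -0.28 and its test were negative (cameraPR adjusted p = 0.167). Of 14 target genes of TGF-beta and BMP, 6 were positive, 2 negative and 6 not past the test, with 6 positive and 3 negative adjusted over the list alone (cameraPR adjusted p = 0.144). SMAD7, an inhibitory SMAD, had 0.52 ± 0.14 and NOG, the BMP antagonist noggin, -1.78 ± 0.32 in the authors' deposited table. Mitochondrially encoded transcripts were not analysed here.

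**Figure D2:**
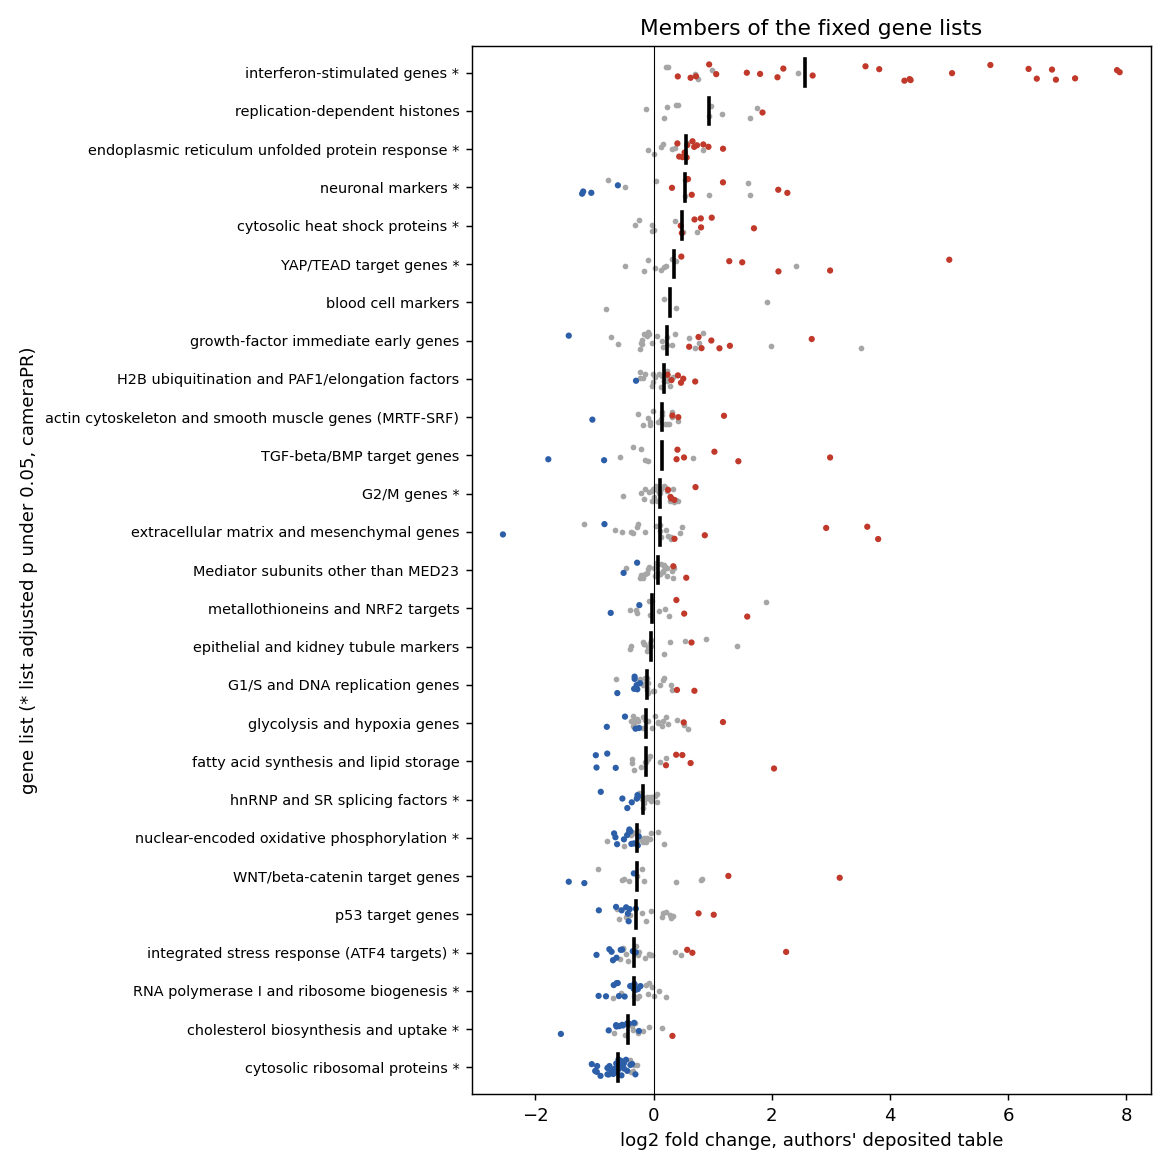
Log2 fold changes in the authors' deposited table (horizontal axis) of the members of the 27 tested gene lists (vertical axis, ordered by median), one point per gene, red or blue where the adjusted p was under 0.05 and grey otherwise, with vertical bars at list medians. Asterisks mark the 6 positive and 6 negative lists past cameraPR, from interferon-stimulated genes with a median of 2.57 to ribosomal proteins with -0.59.

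Across the 27 tested lists, 6 were positive and 6 negative at a cameraPR adjusted p under 0.05 with a preset inter-gene correlation of 0.01. No correlation was estimated, since that needs values per library. Where the genes of a list are regulated together more strongly than the preset value, these p-values are too small.

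Fold changes also differed by chromosome. Among 14536 genes of at least 1 CPM, chromosomes 13 and 5 had median log2 fold changes of -0.31 and -0.25, with 78.6% and 76.9% of their genes negative. Chromosomes 17 and 10 had medians of 0.21 and 0.20, with 71.7% and 71.1% of their genes positive. In a two-sided permutation test with 1000 shuffles of gene positions, 12 of 23 chromosomes passed an adjusted p of 0.05. Chromosomes 13, 5, 17 and 10, and also 2, 3 and 19, had the smallest p the shuffles can give, 0.000999 (adjusted p = 0.00328). The shuffles moved genes and not libraries, so this p does not measure the spread between libraries. On chromosome 2 the medians on either side of the middle gene were -0.22 and 0.02. IFIT1 and IFIT2 lie on chromosome 10 and CCL5 on chromosome 17, with fold changes far above these chromosome medians.

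**Figure D3:**
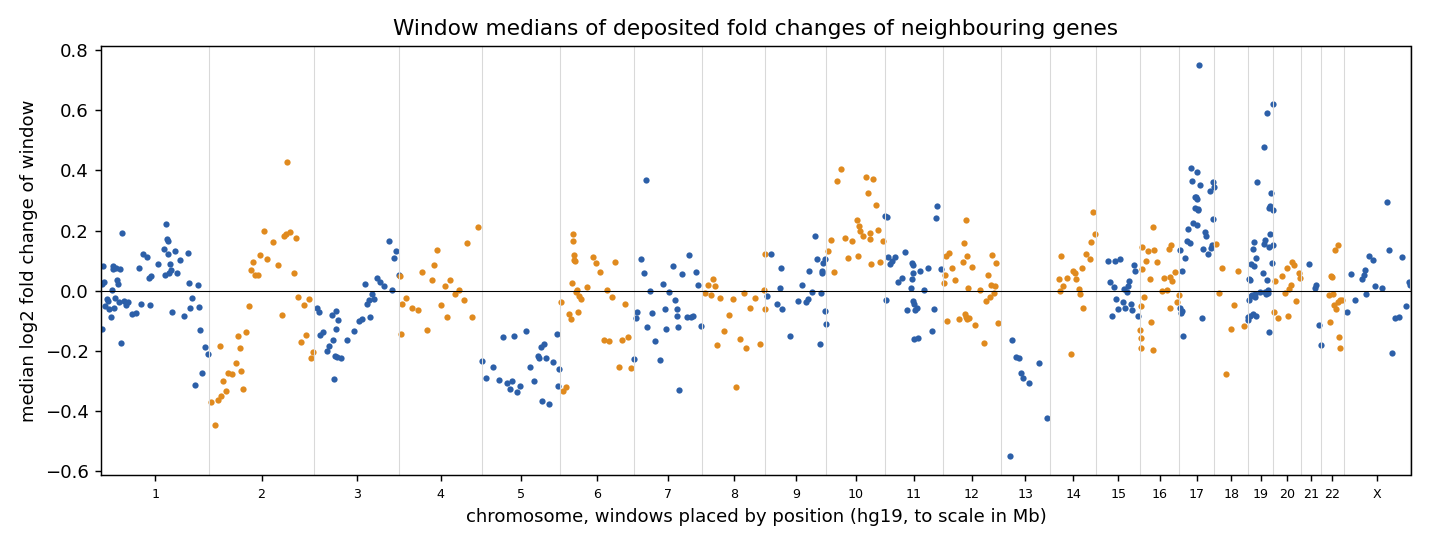
Median log2 fold change in the authors' deposited table (vertical axis) of 568 windows of neighbouring genes placed along chromosomes 1 to 22 and X (horizontal axis, hg19, to scale), one point per window, colours alternating between chromosomes. Windows of chromosomes 5 and 13 lie mostly below 0 and those of chromosomes 10 and 17 mostly above 0, while chromosome 2 has a block of negative windows, then mostly positive windows, then negative windows again.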

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

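All alternatives below were chosen after seeing the data, except the adjustment over all genes with a p, the minimum fold change and, for counts of genes and named genes but not for MED23, the restriction to protein-coding genes. No paired analysis was possible because the columns of values per library carry no replicate numbers; for the same reason leaving out each library, other normalizations, other count tests and a fit of each knockdown were not run. With an absolute log2 fold change of at least 1, the 3196 genes past the threshold became 677 (471 positive, 206 negative), and with an adjusted p under 0.01 they became 1923 (1073 positive, 850 negative), since both are stricter by construction. The count was 2796 adjusted over all genes with a p, 3044 over protein-coding genes only and 2624 at 10 CPM or more. MED23 had adjusted p-values from 0.161 to 0.290 across the 3 alternatives run for it. The alternatives for MED23 and the named genes adjusted the same deposited p over other sets of genes, so no direction could change. They therefore do not check the fold changes. Of 323 results of named genes under alternatives, 321 kept their direction and side of the threshold and 2 lost the call. Of 135 results of the 27 lists, 113 kept both, 9 lost the call, 8 gained it and 5 turned direction without passing the threshold; the cause was not tested. The 5 were glycolysis genes on residuals (adjusted p = 0.749), epithelial markers on residuals (0.950) and against random lists (0.657), and metallothionein and NRF2 genes on ranks (0.710) and residuals (0.381). Lists that gained a call were p53 targets, G1/S genes, H2B ubiquitination and elongation factors and histones. Depth per library is unknown, so no limit from it can be given.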

Other observations

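The grouping of genes by symbol, the genes named in these paragraphs and the tests below were chosen only after the result was seen, except both tests of GC content, length and level. Homeobox genes of the HOXB and HOXA clusters, which pattern the body axis, were higher on the numerator side: 7 of 9 HOXB genes and 6 of 11 HOXA genes were positive and none was negative. Their medians were 0.91 and 0.69 on the log2 scale, with cameraPR adjusted p-values of 2.26e-10 and 0.00841 over 216 symbol groups of at least 8 protein-coding genes, 14 of which passed. All symbol groups, here and below, were tested only with a preset correlation of 0.01. Where the genes of a group are regulated together more strongly than that, such p-values are too small. HOXB4 and HOXB6 stood at 1.45 ± 0.15 (SE) and 1.20 ± 0.11, and HOXA7 and HOXA9 at 1.15 ± 0.21 and 0.97 ± 0.16 in the authors' deposited table. HOXB lies on chromosome 17, whose median was 0.21. The HOXC and HOXD clusters did not pass, with 2 of 9 and 0 of 9 genes positive, none negative and medians of 0.40 and 0.39 (cameraPR adjusted p = 0.656 and 0.387). Of 430 zinc finger genes with the stem ZNF, 71 were positive and 11 negative (adjusted p = 0.0106). Integrin alpha genes had 5 positive and 0 negative among 12 (adjusted p = 0.0493), with ITGA7 at 0.97 ± 0.13 in the authors' deposited table. Mitochondrial ribosomal protein genes were lower, with 19 of 46 MRPL and 11 of 29 MRPS genes negative and none positive (adjusted p = 8.74e-06 and 1.14e-04). Genes with the symbol stem EIF, among them translation initiation factors, had 10 negative and 2 positive genes among 53 (adjusted p = 0.0106). EIF3L, a subunit of the factor that recruits the small ribosomal subunit, stood at -1.03 ± 0.10 in the authors' deposited table.

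HLA genes did not pass as a symbol group, with 6 of 15 positive and 0 negative (cameraPR adjusted p = 0.162). Single genes of class I antigen presentation are given as values. B2M, the light chain of class I molecules, had 1.31 ± 0.09 (SE), the peptide-loading gene TAPBP 1.79 ± 0.14 and the peptide transporter gene TAP1, which is also in the interferon list, 0.63 ± 0.24 in the authors' deposited table. HLA-B and HLA-C stood at 0.72 ± 0.23 and 0.60 ± 0.13, both past the test, while HLA-E at 0.03 ± 0.18 and HLA-F at 0.51 ± 0.22 were not (adjusted p = 0.944 and 0.0832) in the authors' deposited table; these genes are uncertain because they share sequence. Several abundant genes had standard errors far above those of genes of like level, as MED23 did. Among protein-coding genes of at least 10 CPM, the 12 highest ratios ran from 8.67 to 12.9, led by ESRP2, CA2, DDR2, CTSZ and CELF2, and of these 12 genes IFIT2 and COL5A2 passed the test in the authors' deposited table while the other 10 did not.

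MED23 did not differ past the test, while AMOT had a p listed as 0 in the authors' deposited table. The lower bound of the MED23 interval, -0.0873 on the log2 scale, lies above -1, which argues against a mean of the numerator arm lower by at least 2-fold, but says nothing of either knockdown by itself. Summed mean levels of AMOTL1 and AMOTL2 were 0.366 of that of AMOT, too low for AMOT reads assigned to its paralogs to account for its negative fold change. The standard error of MED23, reached by only 0.4% of 1001 genes of like level, goes with libraries of an arm that differ in MED23, but it restates what was already seen, also in a look at the unnamed columns that entered no result, and is no separate evidence. A wrong label, a change of MED23 or AMOT made in some of the cells and an effect of MED23 on AMOT were not tested and stay open.

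Interferon-stimulated genes were positive as a list, and IFNB1 with them. Regression on GC content, length and level kept 92.9% of the list median, which argues against those properties as the whole cause. Blood cells in the cultures are unlikely, since the 14 of their markers in the table had a median of 0.106 CPM and the highest, CD8A, had 2.60. An interferon response of cells in some or all libraries of the numerator side stays open. Whether the knockdown of MED23, its delivery or a difference between cultures set it off was not tested.

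Fold changes shifted along whole chromosomes or large parts of them on chromosomes 13, 5, 17, 10, 2 and 3. Medians on either side of the middle gene were -0.26 and -0.33 on chromosome 13 and 0.18 and 0.26 on chromosome 17. They were -0.26 and -0.24 on chromosome 5 and 0.19 and 0.20 on chromosome 10. They were -0.22 and 0.02 on chromosome 2 and -0.15 and -0.02 on chromosome 3. On chromosome 19 they were 0.00089 and 0.20, but its second part was uneven. Windows there with medians of 0.48 and 0.59 were directly followed by windows of -0.0041 and 0.0020. The spread of chromosome medians of the residuals from GC content, length and level was 0.996 of that of the fold changes, which argues against those properties. Without the called genes the largest shift, on chromosome 13, kept 0.839 of its size, a ratio of shifts and not of the chromosome medians themselves. The median of chromosome 13 went from -0.31 to -0.27, and those of chromosomes 17 and 10 went from 0.21 and 0.20 to 0.14 on both. Leaving genes out by their own test pulls any shifted median towards 0, so these falls do not show how much called genes carry, while what remains argues against a few strongly changed genes as the whole cause. Window medians had an SD of 0.162, above the highest of 1000 shuffles (0.101), but this follows from the chromosome shifts already seen and is no separate evidence, so copy number differences between the compared cells and neighbouring genes regulated together both stay open, as DNA was not analysed here.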
